A study of Rattus norvegicus with 24 samples.

How the data were processed

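Expression was measured in N27 rat cells on 24 arrays of an Illumina rat expression BeadChip, with biotin-labelled cRNA. RNA had been extracted on silica columns with a DNase step and checked for quality on a Bioanalyzer, per the labels. The exposure time and the authors' statistical test are not given in the sources used here. The deposited raw table held, per array, a signal intensity and a detection p-value for each of 22523 probes. The signal intensity was summarized by the authors with GenomeStudio (version not given), on a linear scale, without background subtraction or normalization between arrays, as the values showed. The detection p-value deposited beside each signal compares the probe with the negative controls of its array. The deposited value table held a normalized signal intensity, which the authors had quantile normalized on the linear scale without background subtraction, as found from its values. The raw signals and detection p-values were used for all comparisons, and the authors' table as an alternative.

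Processing used R 4.3.3 with limma 3.58.1 and statmod 1.5.0. Background was corrected by the normal-exponential model with the detection p-values in place of control probes, an offset of 16 was added, arrays were quantile normalized and log2 was taken. The offset draws the folds of dim probes towards 0. Where a group had no array with detection, a fold is given as a lower bound ("at least"), computed against the lowest detected level. Probes with a detection p under 0.05 on at least 4 of the 24 arrays were kept (11470 probes). Of these, 8215 carried a gene name (8042 genes) and 3255 did not, and unnamed probes were counted but not described. On the whole array 13793 probes had a name and 8730 had none, and 41 gene identifiers were missing from the gene table.

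Groups were taken from the sample labels, with 4 arrays each in 6 groups. Slides were read from the array names, with 12 arrays on each of 2 slides. A single limma fit of all 24 arrays, with 18 residual and 4.18 prior degrees of freedom, gave each contrast with two-sided moderated tests. Adjusted p is Benjamini-Hochberg over all kept probes of a contrast, with a threshold of 0.05. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples, and the number of arrays limits the precision. The median SE of a log2 fold was 0.10 for comparisons of 2 groups and 0.14 for interactions. The coating contrast is the citrate response minus the PVP response, and the size by coating contrast is the size difference with citrate minus that with PVP. Interactions are negative where the PVP value is larger.

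Before the data were examined, 31 gene lists were fixed. They covered metallothionein and zinc export, NRF2 antioxidant targets, cytosolic heat shock, ER stress and ATF4 targets, p53 targets and DNA damage, apoptosis regulators, inflammatory and NF-kB targets, interferon response and immediate early genes. Others covered cholesterol synthesis, fatty acid synthesis and lipid storage, glycolysis and hypoxia, respiratory chain, ribosomal proteins, proteasome subunits, G1/S and replication, G2/M, lysosome and autophagy, iron handling, selenoproteins and glutathione, dopaminergic identity and Parkinson genes, and neuronal cytoskeleton and synapse. The rest covered extracellular matrix and adhesion, actin cytoskeleton and SRF targets, endocytosis, core histones and markers of 5 other cell types (astrocytes, oligodendrocytes, microglia and macrophages, endothelium, fibroblasts). Lists were tested with camera at a preset correlation of 0.01, with the probe of the highest mean for each gene. The adjusted p covers 30 lists in the 5 comparisons against a control. The limit of 3 measured genes, which left the fibroblast list out of camera, and the family of list tests on the 5 size and coating contrasts were added after seeing the data. Camera with an estimated correlation and fry were run beside it. The adjusted p of a called list within a slide covers the 20 called lists tested on slide 1 or the 13 on slide 2.

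The genes named were chosen by a rule fixed before the data were examined. In each particle or vehicle comparison it took, among named probes that passed, the 10 largest rises and the 10 largest falls, or all where fewer passed. Where fewer than 3 passed in a direction, the 3 smallest p were given as values that did not pass. In each size or coating contrast it took 5 in each direction. From each fixed list with a passing member or a camera call it took the 3 smallest p. Hmox1, Mt1, Mt2A, Srxn1, Txnrd1, Gclm, Nqo1, Hspa1a or Hspa1b, Ddit3, Cdkn1a, Th and Slc6a3 were always looked up. No named probe was found for Mt2A. Symbols without a clear name (LOC, RGD or predicted) were counted and passed over.

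Alternatives were no background correction, cyclic loess, median scaling, the authors' table, no filter, a filter at a detection p under 0.01 on all arrays, slide as a fixed or random block, each slide alone, the replicate number as a block with and without slide, only the groups compared, array weights, trended and robust moderation, an ordinary two-sample test, other control arrays, and each array left out. Overlaps were set against 20 simulations of unchanged groups that shared simulated control arrays and against 6 splits of the real control arrays. Every comparison was repeated for other splits of its arrays. The pipeline was tested on simulated data with 50 changed probes per fold size. At 1.5-fold it recovered 90% for 10 nm PVP, 86% for 75 nm PVP, 74% for 10 nm citrate, 80% for 75 nm citrate and 80% for the vehicle comparison, and at 4-fold 100%. At 1.25-fold, in that order, it recovered 46%, 38%, 44%, 40% and 48%. For coating at 10 nm, coating at 75 nm and size by coating it recovered 60%, 66% and 64% at 1.5-fold and 14%, 12% and 18% at 1.25-fold. False calls in the 5 comparisons against a control were 8 of 177, 9 of 170, 13 of 174, 9 of 170 and 16 of 182. The simulated noise was independent between probes, so these rates need not hold on the real arrays. No sample was left out.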

Results

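Gene expression was measured on 24 Illumina rat expression BeadChip arrays in N27 cells, an immortalized dopaminergic cell line derived from rat mesencephalon. The cells had been exposed to silver nanoparticles of 10 nm or 75 nm, coated with polyvinylpyrrolidone (PVP, a synthetic polymer) or with citrate (a small anion used to stabilize particles). The design text gives a range of concentrations that did not kill the cells, of which 0.5 ppm is the lowest, while the title of each particle sample gives 0.5 ppm, which was taken as the dose. Controls received HBSS (a balanced salt solution) or citrate without particles. Each of the 6 groups held 4 arrays, and the arrays lay on 2 slides of 12. The HBSS, 10 nm PVP and 75 nm PVP groups each had 1 array on slide 1 and 3 on slide 2. All 4 citrate control arrays lay on slide 1, the 10 nm citrate group had 3 arrays on slide 1 and 1 on slide 2, and the 75 nm citrate group had 2 on each.

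The number of probes detected per array ranged from 9664 to 10479, and the median raw signal from 108 to 124. Mean detected probes were 9948 ± 269 (SD, n = 4) for HBSS, 10166 ± 171 for the citrate control and 9993 ± 127 for 10 nm PVP. They were 10129 ± 287 for 75 nm PVP, 10038 ± 185 for 10 nm citrate and 10174 ± 192 for 75 nm citrate. Arrays of one group correlated across probes at r = 0.994 to 0.996. The first principal component held 11.9% of the variance, with the 8 PVP arrays between -13.7 and -5.01, the 4 HBSS arrays between -2.55 and 1.63, and the 12 arrays with a citrate vehicle or coating between 3.48 and 9.21. On the second component, with 8.04%, the HBSS arrays lay between 7.84 and 12.3 and the other 20 arrays between -6.69 and 2.18.

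**Figure D1:**
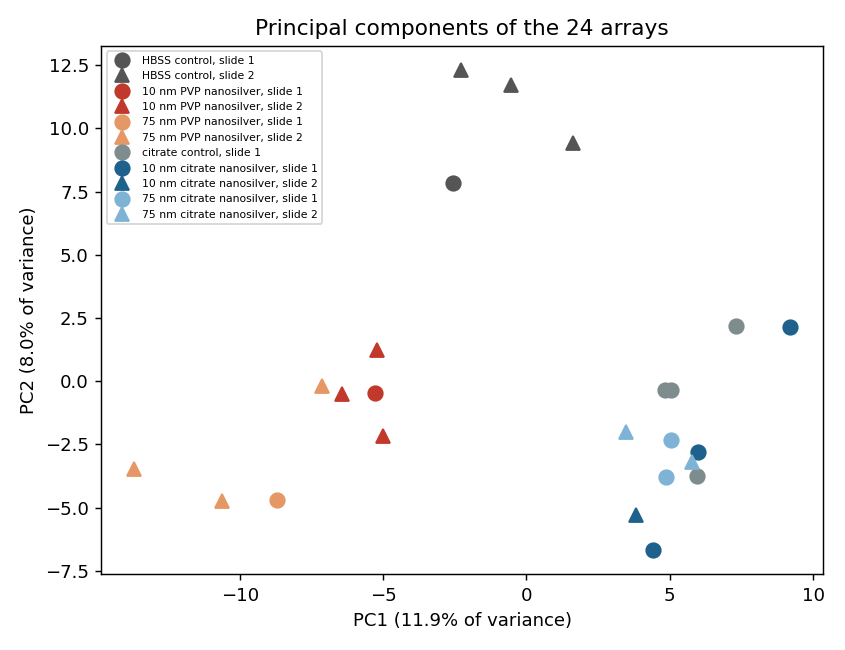
First and second principal component scores of the 24 arrays (log2 normalized intensities, arbitrary units), with colours for the 6 groups and symbols for the 2 slides. The PVP arrays lie on the left (first component -13.7 to -5.01), the citrate groups on the right (3.48 to 9.21) and the HBSS arrays at the top (second component 7.84 to 12.3).

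The first comparison asked what 10 nm PVP-coated silver changed against HBSS. Metallothionein Mt1, which encodes a small cysteine-rich metal-binding protein, rose 4.24-fold (log2 2.08 ± 0.06 SE, adjusted p = 3.86e-16). Its mean was 14.10 ± 0.06 (SD, n = 4, log2) on the 10 nm PVP arrays and 12.01 ± 0.08 on the HBSS arrays. Cyp1a1, a cytochrome P450 that oxidizes aromatic compounds, was detected on all 4 treated arrays and on 0 of 4 HBSS arrays, and it rose at least 2.71-fold (adjusted p = 9.16e-08). The oxidative stress genes Hmox1 (heme oxygenase 1, log2 0.72 ± 0.08) and Nqo1 (a quinone reductase, log2 0.66 ± 0.08) rose with adjusted p of 4.97e-05 and 9.30e-05. Interferon-inducible genes fell, among them Ifit3 (log2 -0.48 ± 0.08), Ifi47 (-0.46) and the guanylate-binding protein genes Gbp5 (-0.44) and Gbp2 (-0.38).

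By fixed list, 1 of 6 measured metallothionein and zinc export genes rose, 0 fell and 5 did not pass, and adjusted over the list alone 3 rose. Slc30a1, a zinc exporter, had a log2 fold of 0.43 (adjusted p = 0.0964) and Mt3 of 0.40 (0.156). The list shifted up with a median of 0.29 (camera adjusted p = 1.23e-05), which was 0.09 without background correction and 0.10 with the authors' table. Neither here nor in the other contrasts was this list tested without Mt1, so its calls are no result apart from Mt1. Of 19 NRF2 antioxidant targets, Hmox1 and Nqo1 rose, 0 fell and 17 did not pass, with 4 rising adjusted over the list alone, and the list shifted up (median 0.13, adjusted p = 8.29e-05). Its further member Osgin1 stood at 0.36 (adjusted p = 0.0652), Gclm at 0.16 and Txnrd1 at 0.15, while Srxn1 was detected on 1 of the 24 arrays. Of 13 interferon response genes, Ifit3, Gbp2, Stat2 (-0.40) and Oas1a (-0.25) fell, 0 rose and 9 did not pass, with 8 falling adjusted over the list alone. That list shifted down with a median of -0.25 (adjusted p = 4.36e-08). These 3 lists kept their calls with an estimated correlation (adjusted p = 0.0046, 0.0166 and 0.000434). Cholesterol synthesis shifted down by a median of -0.11 (-0.07 without background correction) without a gene that passed (0 rose, 0 fell, 16 did not pass, and 0 adjusted over the list alone), with an adjusted p = 0.00771 and an adjusted p = 0.0942 with an estimated correlation. Nsdhl (-0.21), Pmvk (-0.40) and Sqle (-0.14) had its smallest p. Within slide 2, with 3 arrays a group, the adjusted p, over the 13 called lists alone, was 5.26e-06 for the metallothionein list, 0.000106 for NRF2 targets, 1.21e-07 for interferon genes and 0.000492 for cholesterol synthesis. In that order the unadjusted camera p there was 1.62e-06, 4.89e-05, 9.30e-09 and 0.000302, against 1.64e-07, 1.66e-06, 2.90e-10 and 0.000281 on all arrays. Slide 1 held 1 array of each of these groups, with list medians there of 0.26, 0.14, -0.22 and -0.09. The adjusted p of that fit (0.0086, 0.0115, 0.00303 and 0.0679) set 1 array against 1 and count neither for nor against the calls.

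Other genes with the largest rises were Lims1 (log2 1.10 ± 0.23, adjusted p = 0.0278), Tmtc3 (0.84 ± 0.11, 0.000207), the inositol transporter Slc5a3 (0.77 ± 0.16, 0.0284), Slco3a1 (0.64), Wdfy1 (0.63) and the somatostatin receptor Sstr2 (0.60). HBSS lay below the mean of the other 5 groups, which includes 10 nm PVP, for Lims1 (-1.04), Tmtc3 (-0.88), Slc5a3 (-0.61) and Wdfy1 (-0.67). Without particles, the citrate control also exceeded HBSS for Tmtc3 (0.71) and Wdfy1 (0.59). The rises of these 4 genes need not be particular to 10 nm PVP. Besides the interferon genes, the largest falls were Lat (-0.58 ± 0.13, adjusted p = 0.0430), Cep57l1 (-0.55), Mief2 (-0.53), Atp6v0a1 (-0.45), Prpf38b (-0.44), lamin B2 Lmnb2 (-0.43) and Arhgap39, which was at least 1.06-fold lower. Among inflammatory and NF-kB targets, Ptgs2 (cyclooxygenase 2, 0.53) and Il1rl1 (0.54) rose, 0 fell and 18 did not pass, with 2 rising and 4 falling adjusted over the list alone. Cyclin E2 (Ccne2) rose by 0.38, as the only gene of 25 G1/S and replication genes that passed. Birc2 (-0.26) was the only one of 19 apoptosis regulators that fell, Sparc (-0.38) the only one of 18 extracellular matrix genes, and 0 rose in either list. S100a4, the 1 measured gene of the fibroblast list, fell by 0.28.

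In all, limma called 48 probes higher and 30 lower, of 11470 tested, and 18 of the risers and 0 of the fallers exceeded 1.5-fold. The calls included 13 higher and 4 lower probes without a gene name. Over all tested probes, the 4 arrays of each group were fully apart for 7.79%, where chance gives 2.86%. With median scaling in place of quantile normalization, 46 were higher and 15 lower. With slide as a block 66 were called, 65 of them shared. Both groups lay alike on the slides, so the block left every fold as it was, those of Atp6v0a1 (-0.45), Mief2 (-0.53) and Sstr2 (0.60) included, which then missed the threshold (adjusted p = 0.0532, 0.0539 and 0.0517). Within slides 1 and 2 alone 1 and 6 were called. Mt1 stood at 2.21 within slide 1 and 2.04 within slide 2. The count was 26, 47, 47 and 20 without 10 nm PVP replicates 1, 2, 3 and 4, and 26 and 20 without HBSS replicates 1 and 2. The HBSS arrays differed from the mean of the other 5 groups in 183 probes, and with the citrate control in their place, an alternative added after seeing the data, 391 were called, 41 of them shared.

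**Figure D2:**
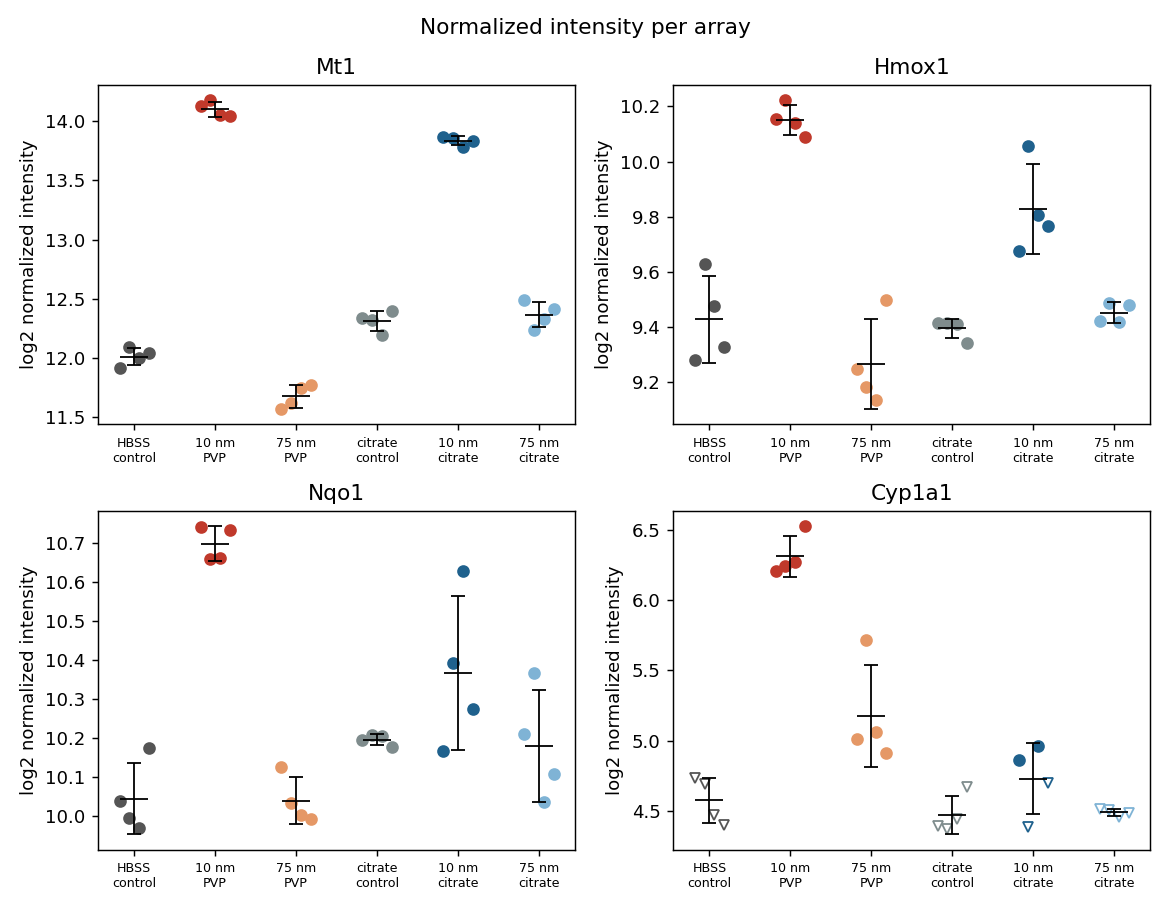
Log2 normalized intensity of Mt1, Hmox1, Nqo1 and Cyp1a1 on each of the 24 arrays by group, with horizontal bars for the mean and error bars for the SD of 4 arrays and open triangles for arrays on which the probe was not detected. Mt1 averaged 14.10 and 13.83 in the 10 nm PVP and 10 nm citrate groups and 11.68 to 12.37 in the other 4 groups.

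The second comparison set 75 nm PVP-coated silver against HBSS. More probes passed here than at 10 nm, with 209 higher and 248 lower, but most changes were small, and 45 risers and 3 fallers exceeded 1.5-fold. Mt1 fell by 0.33 (log2 -0.33 ± 0.06 SE, adjusted p = 0.0058), with a mean of 11.68 ± 0.10 (SD, n = 4) against 12.01 ± 0.08. The largest rise was that of Tmtc3 (log2 1.19 ± 0.11, adjusted p = 2.30e-06), followed by Lims1 (0.94) and Slc5a3 (0.93). For these 3 genes HBSS also lay below the mean of the other 5 groups, which includes 75 nm PVP (-0.88, -1.04 and -0.61). The copper-transporting ATPase gene Atp7a rose by 0.77 ± 0.13 (adjusted p = 0.00281), and Cyp1a1, detected on all 4 treated arrays, rose at least 1.23-fold (adjusted p = 0.0171). For Atp7a too HBSS lay below the mean of the other 5 groups (-0.58). Hmox1 (-0.16, adjusted p = 0.309) and Nqo1 (-0.01, 0.986) did not pass.

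Further rises were those of Sv2b, a synaptic vesicle glycoprotein gene (0.78), Carnmt1 (0.76), Slco3a1 (0.65), Trps1 (0.64), the death-receptor kinase gene Ripk1 (0.62) and Pi4k2a (0.62). HBSS also lay below the mean of the other 5 groups for Sv2b (-0.76), Carnmt1 (-0.47), Ripk1 (-0.57) and Pi4k2a (-0.49). That mean includes the particle group compared here. The rises of these genes need not be particular to that group. Falls were led by the calpain gene Capn3 (-0.63 ± 0.13, adjusted p = 0.00943), Abtb1 (-0.59), Pmvk (-0.53), Spag7 (-0.52), Pdzk1ip1 (-0.51) and S100a1 (-0.51). They went on with the gamma-secretase subunit gene Psenen (-0.50), Nrm (-0.49), Rwdd2a (-0.49) and Irgc, which was at least 1.15-fold lower. For Spag7 HBSS lay above the mean of the other 5 groups (0.51), and with the citrate control in place of HBSS its fold was 0.12. Cholesterol synthesis shifted down (median -0.18, adjusted p = 0.00357, and adjusted p = 0.0669 with an estimated correlation). Of its 16 genes, Pmvk and Sqle (squalene epoxidase, -0.20) fell, 0 rose and 14 did not pass, with 6 falling adjusted over the list alone. The respiratory chain list moved down by a median of -0.08 (adjusted p = 0.0423, and adjusted p = 0.383 with an estimated correlation). Of its 48 genes 7 fell, among them the complex I genes Ndufa1 (-0.35) and Ndufb7 (-0.34), 3 rose, among them Uqcrc1 of complex III (0.29), and 38 did not pass. Adjusted over the list alone 11 fell and 3 rose. Within slide 2 the adjusted p, over the 13 called lists alone, was 0.00106 for cholesterol synthesis and 0.00715 for the respiratory chain. The unadjusted camera p there was 0.000731 and 0.0055, against 9.51e-05 and 0.0031 on all arrays. Within slide 1 the medians were -0.19 and -0.06, and the adjusted p (0.0115 and 0.276) set 1 array against 1, which counts neither for nor against the calls. Camera did not call the metallothionein list, where Mt1 alone fell, 0 rose and 5 did not pass (median 0.09, test direction down, adjusted p = 0.936).

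In lists without a camera call, the selenoprotein and glutathione genes Selenow (-0.42 ± 0.05, adjusted p = 0.00037), Selenok (-0.25) and Gstt2 (-0.26) fell, 0 rose and 16 did not pass. Single members passed in several others. Among ER stress and ATF4 targets Cebpb (0.29) rose and Nupr1 (-0.28) fell, and among inflammatory targets Ptgs2 (0.51) rose and Sod2, mitochondrial superoxide dismutase (-0.22), fell. Ccne2 (0.44) rose and E2f1 (-0.32) fell, the latter with the same fold and an adjusted p = 0.0510 under the slide block, and the mitotic kinase gene Aurkb rose by 0.23. Vegfa (0.38) rose and Ankrd37 (-0.36) fell among glycolysis and hypoxia genes. The ribosomal protein genes Rpl31 (-0.35) and Rps23 (-0.24) fell, as did Stat2 (-0.38), Birc2 (-0.23), Sparc (-0.41) and the fibroblast-list gene S100a4 (-0.35). Rises were measured for Atp6v1a, a lysosomal proton pump subunit (0.41), Gch1, which makes the cofactor of tyrosine hydroxylase (0.24), microtubule-associated Map1b (0.37), Loxl1 (0.26) and vimentin Vim (0.31). A second probe of Map1b (0.08) and of Loxl1 (0.17) did not pass.

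Of the 457 called probes, 74 higher and 59 lower had no gene name. Over all tested probes, the groups were fully apart for 9.83%, where chance gives 2.86%. With slide as a block, which left the folds as they were since both groups lay alike on the slides, 437 were called, 428 of them shared. Within slide 1, with 1 array a group, 0 were called (4 of the 457 had the opposite sign), and within slide 2 limma called 4. Slide 2 gave a Mt1 log2 fold of -0.33 and slide 1 of -0.34. The count was 218 and 212 without 75 nm PVP replicates 1 and 2, and 296, 294 and 292 without HBSS replicates 1, 3 and 4. Fitted on the 8 arrays of the 2 groups alone, 20 passed, and with the citrate control in place of HBSS 922, 228 of them shared.

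The third comparison set 10 nm citrate-coated silver against the citrate control. Mt1 rose 2.87-fold (log2 1.52 ± 0.06 SE, adjusted p = 3.54e-13), from 12.31 ± 0.08 (SD, n = 4) to 13.83 ± 0.04, and was the 1 probe of 11470 that passed. The count was 22 without background correction, 20 with the authors' table, 16 with trended and robust moderation and 6 with the stricter filter, Mt1 among them each time. Hmox1 (0.43 ± 0.08, adjusted p = 0.110), Slc30a1 (0.47 ± 0.12, 0.218), Eif1a (0.31, 0.112) and Selenoo (0.31, 0.144) did not pass. Lower values that did not pass were those of Uggt1 (-0.40, 0.110), Tenm3 (-0.34, 0.141) and Tgm1 (-0.30, 0.155). Nqo1 stood at 0.17 (adjusted p = 0.539), and Cyp1a1 was detected on 2 of the 4 treated arrays and on 0 of 4 controls.

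The metallothionein list shifted up (adjusted p = 0.0333, and adjusted p = 0.111 with an estimated correlation), with 1 riser, 0 fallers and 5 genes not passing, and 2 risers adjusted over the list alone. Only 3 of its 6 genes were higher, and the adjusted p was 0.0652 with slide as a block and 0.184 within slide 1. Cholesterol synthesis shifted down by a median of -0.09 (-0.05 both without background correction and with the authors' table, adjusted p = 0.0389, and adjusted p = 0.157 with an estimated correlation), with 0 of 16 genes rising or falling and 1 falling adjusted over the list alone. That list kept its call with slide as a block, with an adjusted p = 0.0217 and a median of -0.04 within slide 1. The adjusted p within slide 1 covers the 20 called lists alone. The unadjusted camera p there was 0.0117, against 0.00233 on all arrays. Its smallest p belonged to Cyp51 (-0.41), Sqle (-0.16) and Hsd17b7 (-0.29). The NRF2 list did not pass (median 0.06, adjusted p = 0.148), nor did the interferon list (-0.06, adjusted p = 0.191). With slide as a block and within slide 1, Mt1 was again the single call (log2 1.51 and 1.52), and slide 2 held no citrate control array. By unadjusted p, 1032 probes lay under 0.05, against 573.5 expected by chance.

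The fourth comparison set 75 nm citrate-coated silver against the citrate control, and 0 probes passed. The smallest adjusted p was 0.637. Mt1 differed by 0.05 ± 0.06 (SE, adjusted p = 0.957), with means of 12.37 ± 0.11 (SD, n = 4) and 12.31 ± 0.08. The smallest p belonged to C1qbp (0.27), RT1-CE15 (0.30) and Ager (0.54) on the higher side and to Ep400 (-0.40), Uggt1 (-0.32) and Pank1 (-0.28) on the lower, all at an adjusted p = 0.637. Hmox1 (0.06) and Nqo1 (-0.02) did not pass either. None of the 30 lists passed, and the metallothionein and zinc export list had a median of 0.05 (adjusted p = 0.561). By unadjusted limma p, 652 probes lay under 0.05 against 573.5 expected by chance, an ordinary two-sample test called 1 probe, and every other tool called 0. The slide block and slide 1 alone also gave 0.

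The vehicle comparison set the citrate control against HBSS, without particles in either. The kinase-like stress gene Trib3 (log2 0.49 ± 0.09 SE, adjusted p = 0.00642), the mTORC1 inhibitor gene Ddit4 (0.38) and the mitophagy receptor gene Bnip3 (0.46 ± 0.07, adjusted p = 0.00118) rose. Pdk1, a kinase that inhibits pyruvate dehydrogenase, rose by 0.35, and Mt1 rose 1.23-fold (0.30 ± 0.06, adjusted p = 0.0273). The interleukin 33 receptor gene Il1rl1 fell by 0.70 (adjusted p = 0.00161), the chemokine gene Cxcl2 by 0.48 and Ccn2, a matricellular growth factor gene, by 0.44 (adjusted p = 0.000288).

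The largest rises were those of Tmem220 (0.77 ± 0.12), Tmtc3 (0.71 ± 0.11), Wdfy1 (0.59), Nfix (0.59), Stau2 (0.56), Tfdp2 (0.54), Bbs4 (0.53), Uba7 (0.53), Eif4e3 (0.52) and Slc16a6 (0.50). HBSS also lay below the mean of the other 5 groups, which includes the citrate control, for Tmem220 (-0.57), Tmtc3 (-0.88), Wdfy1 (-0.67), Nfix (-0.46) and Stau2 (-0.56). After Il1rl1, the largest falls were Spag7 (-0.64 ± 0.13), the mitochondrial dicarboxylate carrier gene Slc25a10 (-0.62), the EGF receptor ligand gene Areg (-0.54), Cited1 (-0.52), Krt23 (at least 1.16-fold lower), Rwdd2b (-0.45) and Fblim1 (-0.43). For Spag7 (0.51) and Cited1 (0.47) HBSS lay above that mean of the other 5 groups. ER stress and ATF4 targets shifted up by a median of 0.06 (adjusted p = 0.00771, and adjusted p = 0.111 with an estimated correlation), where 2 of 28 genes rose, 0 fell and 26 did not pass, with 3 rising adjusted over the list alone. Of 23 glycolysis and hypoxia genes 2 rose, 0 fell and 21 did not pass, with 5 rising and 1 falling adjusted over the list alone (median 0.07, adjusted p = 0.0394, and adjusted p = 0.0946 with an estimated correlation). Of 16 cholesterol synthesis genes Mvd alone fell (-0.32), 0 rose and 15 did not pass, with 2 falling adjusted over the list alone (median -0.12, or -0.08 without background correction, adjusted p = 0.0232, and adjusted p = 0.111 with an estimated correlation). The glycolysis and cholesterol calls ended under median scaling (adjusted p = 0.0567 and 0.0609), with medians of 0.05 and -0.11. All 3 lists kept their calls with slide as a block. Within slide 1, where 4 citrate control arrays met 1 HBSS array, the medians were 0.07 for ER stress, 0.07 for glycolysis and -0.15 for cholesterol synthesis. The fit within slide 1 assumed the lone HBSS array to vary like the other groups, so no p is given. Gja1, connexin 43, from the astrocyte list fell by 0.27, with 0 of 3 measured genes rising, 2 not passing and 1 falling adjusted over the list alone.

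Here 54 probes were higher and 35 lower, and over all tested probes the groups were fully apart for 8.64%, where chance gives 2.86%. Blocking by slide left 30 called (16 higher, 14 lower, 29 of them shared), and with slide as a random block 150. The 60 probes that lost their call under the block kept their direction, with a median size of 0.38 before and 0.37 after (log2), while their median SE was 0.083 before and 0.094 after. Mt1, Ddit4, Pdk1, Wdfy1, Stau2, Tfdp2, Bbs4, Uba7, Spag7, Slc25a10, Areg, Cited1, Krt23, Mvd and Gja1 then missed the threshold, with adjusted p from 0.0517 (Mt1) to 0.153 (Areg). Under the block Mt1 stood at 0.34, Ddit4 at 0.30, Pdk1 at 0.36, Wdfy1 at 0.65, Stau2 at 0.51, Spag7 at -0.61, Slc25a10 at -0.54, Areg at -0.47, Mvd at -0.32 and Gja1 at -0.25. Within slide 1, 0 passed. The count was 47, 43 and 54 without HBSS replicates 1, 2 and 3, and 39, 56, 33 and 36 without citrate control replicates 1, 2, 3 and 4.

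**Figure D3:**
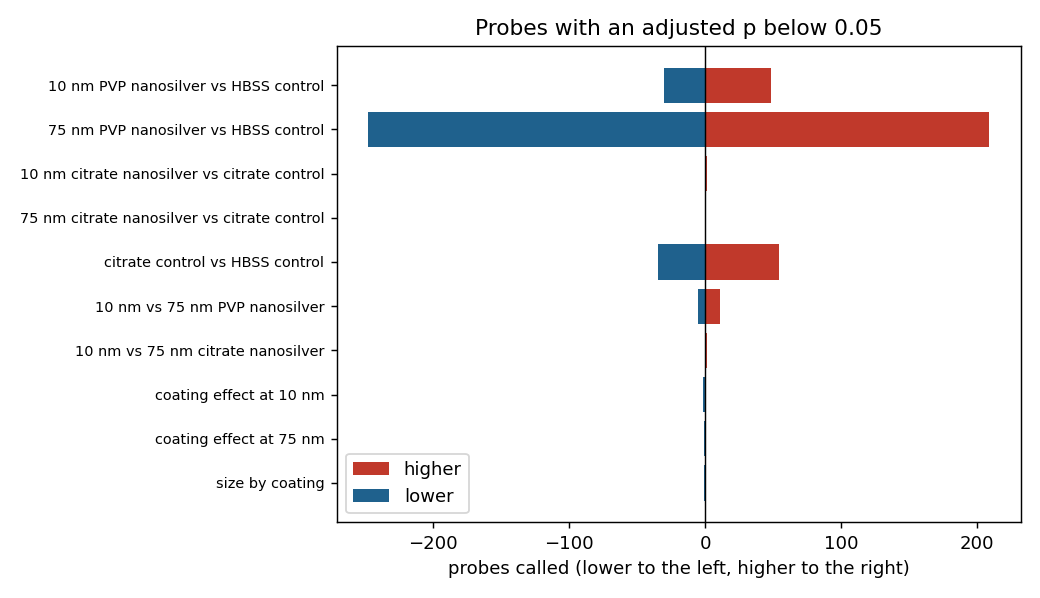
Number of probes with an adjusted p under 0.05 in each of the 10 contrasts, with higher probes to the right and lower probes to the left of 0. The 75 nm PVP comparison has the longest bars (209 higher, 248 lower), and 75 nm citrate has 0.

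**Figure D4:**
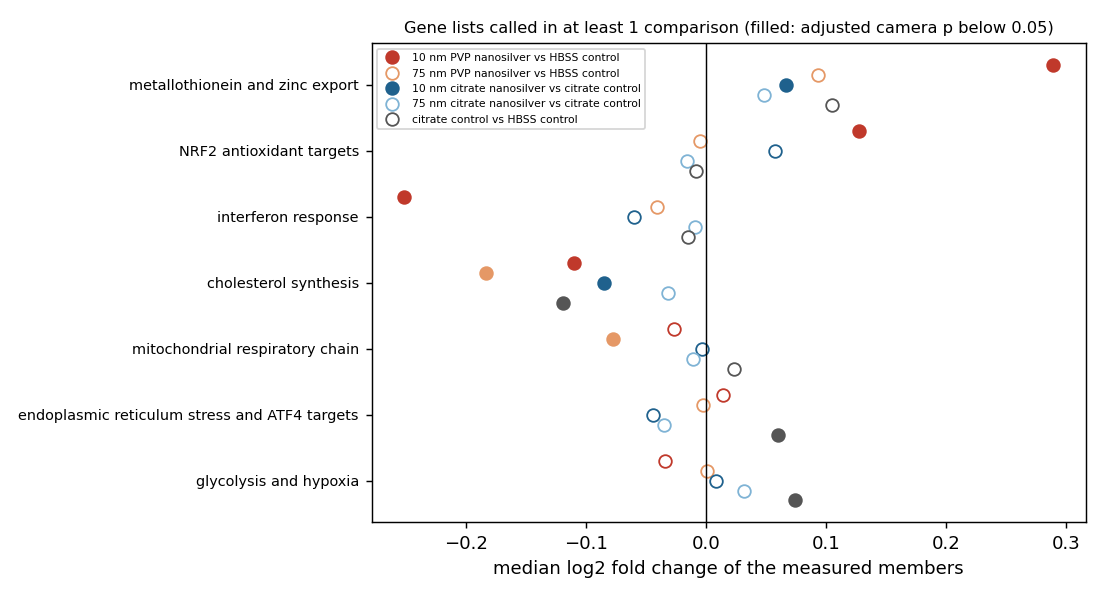
Median log2 fold change of the measured members of 7 gene lists called in at least 1 of the 5 comparisons against a control, with filled points where the camera adjusted p was under 0.05. Metallothionein and NRF2 lists lie highest for 10 nm PVP (0.29 and 0.13), and the interferon list lies lowest there (-0.25).

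Particle size was compared directly within each coating. For PVP, 11 probes were higher at 10 nm than at 75 nm and 5 lower. Mt1 was 5.35-fold higher (log2 2.42 ± 0.06 SE, adjusted p = 1.51e-17), Cyp1a1 was higher by 1.14 ± 0.14 (0.000108), Hmox1 by 0.88 ± 0.08 (2.62e-06) and Nqo1 by 0.66 ± 0.08 (0.000108). Mycn, an oncogenic transcription factor gene, was at least 1.33-fold higher, and Slc30a1 (0.57), Syt1 (0.44), Gstt2 (0.36), Selenow (0.30), Gstm2 and Psenen were higher too, the last 2 named after their values were seen. Ifit3 (-0.52), Oas1a (-0.35), Cep57l1 (-0.60), Prpf38b (-0.56) and 1 unnamed probe were lower at 10 nm.

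Among lists, metallothionein and zinc export genes were higher at 10 nm PVP (Mt1 and Slc30a1 of 6 rose, 0 fell, 4 did not pass, by sign 4 higher and 2 lower, median 0.14, adjusted p = 0.000355), as were NRF2 targets (2 of 19 rose, 0 fell, 17 did not pass, median 0.11, adjusted p = 8.88e-06). Both without background correction and with the authors' table these medians were 0.04 and 0.06. Adjusted over the list alone 2 and 4 rose. Interferon genes were lower (0 of 13 rose, 2 fell, 11 did not pass, 5 falling adjusted over the list alone, median -0.17, adjusted p = 4.46e-06). These 3 calls held with an estimated correlation. Selenoprotein and glutathione genes shifted up by a median of 0.04, or 0.09 with median scaling (2 of 19 rose, also adjusted over the list alone, 0 fell and 17 did not pass, adjusted p = 0.00903, and adjusted p = 0.0986 with an estimated correlation). Within slide 2 the adjusted p, over the 13 called lists alone, was 0.000106 for the metallothionein list, 2.07e-06 for NRF2 targets, 1.35e-07 for interferon genes and 0.0186 for selenoprotein genes. In that order the unadjusted camera p there was 4.41e-05, 4.78e-07, 2.07e-08 and 0.0157, against 7.10e-06, 1.18e-07, 2.97e-08 and 0.000482 on all arrays. Within slide 1 the medians were 0.11, 0.10, -0.19 and 0.08, and the adjusted p (0.0136, 0.0458, 0.0319 and 0.0136) set 1 array against 1, which counts neither for nor against the calls. A slide block left these folds as they were and kept all 16 calls, and within slides 1 and 2 there were 1 and 4, with Mt1 at 2.55 and 2.38. The count was 10 without 10 nm PVP replicate 1 and 10 without 75 nm PVP replicate 1.

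For citrate, Mt1 was 2.76-fold higher at 10 nm than at 75 nm (log2 1.47 ± 0.06 SE, adjusted p = 7.50e-13) and was the single call, also with slide as a block and within slides 1 and 2 (1.47 and 1.46). Or2c1 (0.50, adjusted p = 0.384), Hmox1 (0.38, 0.384), Ces2g (0.44, 0.408), Olig3 (-0.41, 0.378), Tm9sf4 (-0.38, 0.384) and Zfp689 (-0.50, 0.384) did not pass. Of 19 NRF2 targets 0 rose or fell, 1 rising adjusted over the list alone, and the list shifted up by a median of 0.03 (0.02 with cyclic loess and 0.07 with median scaling, adjusted p = 0.0348, and adjusted p = 0.182 with an estimated correlation). Within slide 1, with 3 arrays against 2, its adjusted p over the 20 called lists alone was 0.0448. The unadjusted camera p there was 0.0314, against 0.00209 on all arrays. Within slide 2, with 1 array against 2, the median of the list was 0.05. Without 75 nm citrate replicate 2 the count was 2.

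Coating was tested as the difference between the citrate response and the PVP response, each against its own control. At 10 nm the response of Mt1 was larger with PVP (interaction log2 -0.57 ± 0.09 SE, adjusted p = 0.0159). The citrate control exceeded HBSS by 0.30 for Mt1 without particles, and that difference between the controls is part of the interaction value. Cyp1a1 passed as well, on the PVP side (adjusted p = 0.00172). Its probe was detected on 0 of 4 arrays of either control, so the size of that difference is not given. Values for Nqo1 (-0.49, 0.339), Tmtc3 (-0.77, 0.142), Tenm3 (-0.46, 0.209), Lat (0.91, 0.170), Frs2 (0.54, 0.339) and Sema3c (0.66, 0.339) did not pass. The metallothionein list responded more to PVP (1 of 6 genes passed, also adjusted over the list alone, median -0.26, or -0.08 without background correction and -0.09 with the authors' table, adjusted p = 0.00639). The interferon list fell further with PVP (0 of 13 genes passed, also adjusted over the list alone, median 0.19, or 0.12 without background correction, adjusted p = 0.0012). Both held with an estimated correlation (adjusted p = 0.0454 and 0.0145) and with slide as a block. Within slide 1 the medians were -0.22 and 0.05, and the adjusted p (0.0217 and 0.0273) rest on 1 HBSS array and 1 of 10 nm PVP. At 75 nm Tmtc3 differed (-1.02 ± 0.15, adjusted p = 0.0135), as the 1 probe that passed. Much of that value is the difference between the controls, as the citrate control exceeded HBSS by 0.71 for Tmtc3 without particles. The count at 75 nm was 75 without background correction, 83 with the authors' table, 59 with trended and robust moderation and 27 with the stricter filter. Carnmt1 (-0.73, 0.101), Psenen (0.52, 0.0945), Akap9 (-0.59, 0.101), Ddx6 (-0.48, 0.101), Prr13 (0.48, 0.101) and Sh2d4a (0.46, 0.101) did not pass.

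With slide as a block the counts at 10 nm and 75 nm stayed at 2 and 1, within slide 1 both were 0, and slide 2 held no citrate control array. Without either 10 nm PVP replicate 2 or 3, HBSS replicate 1 or 2, or citrate control replicate 1 or 3 the count at 10 nm was 1, and without 10 nm citrate replicate 2 or 3 or citrate control replicate 2 it was 3. At 75 nm it was 0 without 75 nm PVP replicate 1 or 3 or citrate control replicate 1 or 3, 2 without 75 nm citrate replicate 2 or HBSS replicate 4, and 41 without 75 nm PVP replicate 4.

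The size difference itself depended on coating for Mt1, which differed more between 10 nm and 75 nm with PVP (-0.95 ± 0.09 SE, adjusted p = 5.30e-06). The controls cancel in this contrast. Cyp1a1, detected on 0 of 4 arrays at 75 nm citrate (adjusted p = 0.406), Sdf2l1 (-0.57, 0.406), Pdzk1ip1 (-0.41, 0.406), Prr5l (0.75, 0.406) and Itpr1 (0.42, 0.406) did not pass. The metallothionein list (1 of 6 genes passed, also adjusted over the list alone, median -0.14, or -0.04 without background correction and -0.05 with the authors' table, adjusted p = 0.0012) and the interferon list (0 of 13 passed, 2 adjusted over the list alone, median 0.14, adjusted p = 0.00302) differed likewise. Both held with an estimated correlation (adjusted p = 0.0180 for each). Mt1 was also the single call with slide as a block, and within slides 1 and 2 there were 0 (Mt1 at -1.08 and -0.91), while within slide 2 the adjusted p was 0.0332 for the metallothionein list and 0.000143 for the interferon list. Within slide 1 it was 0.0136 and 0.273, with medians of -0.21 and 0.10. Slide 1 held 1 array of each PVP group and slide 2 held 1 of 10 nm citrate. Without 10 nm PVP replicate 4 or 75 nm PVP replicate 2 the count was 2.

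The responses to both PVP sizes shared 43 called probes in the same direction and 1, Mt1, in opposite directions. Independent lists of these lengths would share 1.52. At an unadjusted limma p under 0.01 they shared 218 probes in the same direction. Simulated unchanged groups that shared simulated control arrays had a mean of 15.95 and at most 23 in common. All arrays of the simulation were drawn, with noise independent between probes. It thus holds no deviation of the real HBSS arrays and cannot separate a shared response from such a deviation. Log2 folds correlated across probes at r = 0.636 (0.499 simulated), with a covariance of 0.0152 (0.00656 simulated), where probes are not independent replicates. When the HBSS arrays were split so that each size had its own 2, r averaged 0.258 and the shared calls 4 (2 to 10). The probes shared at an unadjusted limma p under 0.01 then averaged 78.3. Both citrate sizes correlated at r = 0.539 (0.497 simulated), with a covariance of 0.00815 (0.00652 simulated) and r = 0.117 with split controls. Across coatings, with no array shared, r was 0.198 at 10 nm and 0.115 at 75 nm. The citrate control against HBSS shared 10 calls in the same direction and 2 in opposite directions with 10 nm PVP, and 23 and 1 with 75 nm PVP. Independent lists would share 0.318 and 1.74, and with split HBSS arrays the means were 0.833 and 2.17. At an unadjusted limma p under 0.01 they shared 102 and 112 (simulated means 16.15 and 15.65, at most 25 and 22). Here r was lower than in the simulation, at 0.416 (0.504 simulated) and 0.412 (0.497), with covariances of 0.0088 (0.00663) and 0.00989 (0.00654). With split HBSS arrays r averaged 0.058 and 0.089, and the probes shared at an unadjusted limma p under 0.01 averaged 25.3 and 39.8. The 9 probes called higher in all 3 comparisons against HBSS included Stau2, Tmtc3 and Wdfy1 and, named after its values were seen, Loxl2, with 5 unnamed. A second probe of Wdfy1 rose at 75 nm PVP (0.50, adjusted p = 0.0168) and with citrate (0.49, 0.0427) and stood at 0.38 at 10 nm PVP (0.145), where it did not pass.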

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

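The tests of the 75 nm PVP pattern and the tests of the interferon list against 75 nm PVP and within slide 2 were chosen only after the results were seen, and the other tests here were chosen before.

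In 6 of 90 groups of 4 arrays checked, 1 array lay far from the other 3, where chance gives 4.5. Citrate control replicate 1 had 9911 detected probes against 10229 to 10263 (gap over range 0.903). 10 nm PVP replicate 3 had a median raw signal of 122.5 against 113.4 to 114.3 (0.901). Ddit3 was 10.27 in citrate control replicate 3 against 10.06 to 10.08 (0.934), and Gclm was 10.93 in 10 nm PVP replicate 1 against 11.10 to 11.13 (0.833). Hmox1 was 9.34 in citrate control replicate 1 against 9.41 in the others (0.961), and Ifit3 was 8.54 in 75 nm PVP replicate 1 against 8.45 to 8.46 (0.844).

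Responses that differed by coating, by the test of the interaction itself, were Mt1 (-0.57) and Cyp1a1 at 10 nm and Tmtc3 (-1.02) at 75 nm. These values also hold the difference between the 2 controls. Without particles, the citrate control exceeded HBSS by 0.30 for Mt1 and 0.71 for Tmtc3. The fitted Cyp1a1 value (-1.48) is no measured size, as its probe was detected on 0 of 4 arrays of either control. At 10 nm the metallothionein list (adjusted p = 0.00639) and the interferon list (adjusted p = 0.0012) differed too. The size difference depended on coating for Mt1 (-0.95), the metallothionein list (adjusted p = 0.0012) and the interferon list (adjusted p = 0.00302).

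75 nm PVP differed from HBSS in 457 probes. A single array as the whole source is argued against by the 212 probes still called without 75 nm PVP replicate 2, the lowest of 8 counts. Slide is argued against by the layout, alike in both groups. The median fold of these probes within slide 2 was 1.03 times that on all arrays. That ratio adds little, as the probes were chosen on all arrays and slide 2 held 3 arrays of each group. Deviating HBSS arrays could account for part, and the test of this cannot decide. Probes chosen with 2 of the 75 nm PVP arrays differed between the other 2 and the citrate-vehicle groups by 0.395 to 0.780 of their difference from HBSS over 6 splits. That missed the bound of at least 0.5 in every split that would have argued against deviating HBSS arrays. Yet the same HBSS arrays served to choose the probes and to form the ratio, which lowers it even without such a deviation. The PVP coating without silver cannot be told apart from the particles, as the groups held 0 arrays of it.

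The HBSS arrays differed from the mean of the other 5 groups in 183 probes (65 higher, 118 lower), with Lims1 (-1.04), Tmtc3 (-0.88), Mt1 (-0.85), Sv2b (-0.76) and Wdfy1 (-0.67) lower, and the other groups' mean holds the particle responses, such as that of Mt1 at 10 nm. With slide as a block 179 were called and with the number of detected probes as a covariate 198, which argues against either as the whole source. Without HBSS replicate 1 the count was 74, without replicate 2 it was 102, and without replicates 3 and 4 it was 142 and 149, so 1 array alone is argued against. The 75 nm PVP arrays differed from the other groups in more probes (931). No biological explanation was tested, and a difference in handling or medium between HBSS and the other cultures may remain, since neither slide (179) nor detection (198) covers it.

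The interferon list was lower at 10 nm PVP than in HBSS. High HBSS arrays alone are argued against by the comparison with 75 nm PVP, which uses no HBSS array (adjusted p = 4.46e-06). Without each of the 8 arrays in turn the highest p was 9.48e-09, without HBSS replicate 1, and within slide 2, which argues against slide, the p was 9.30e-09 (adjusted p = 1.21e-07). The list may thus respond to the 10 nm PVP exposure, as a hypothesis found and tested on the same data, and the coating without silver stays open.

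Other splits of the same arrays tested whether the counts could come from chance. Only the real split, 1 of 35, reached the probe counts of 10 nm PVP (78, highest other split 1) and 75 nm PVP (457, highest other 3). The same held for the vehicle comparison (89, highest other 1), the sizes with PVP (16, highest other 2) and the sizes with citrate (1, highest other 0). For the coating contrast at 10 nm (2, highest other 2) 2 of 100 regroupings were as large, the real one included. These values argue against chance but do not exclude it. With 35 splits, 1 of 35 is the smallest share possible, and it was not corrected over the tests. The real vehicle split also set 3 more citrate control than HBSS arrays on slide 1, an imbalance few other splits had. The count alone did not argue against chance for 10 nm citrate (1, highest other 1, 2 of 35), the coating contrast at 75 nm (1, highest other 1, 5 of 100) and size by coating (1, highest other 3, 9 of 100). A count of 1 does not show how strong that call is, such as Mt1 at 10 nm citrate (adjusted p = 3.54e-13) and in size by coating (5.30e-06). For 75 nm citrate (0, highest other 1, 35 of 35) every split reaches a count of 0, so the splits say nothing. Numbers of lists argued against chance, with the same limit, for 75 nm PVP (2, highest other 1) and 10 nm citrate (2, highest other 1), each with 1 of 35. Yet those lists lost their calls with an estimated correlation. The number of lists cannot decide on chance for 10 nm PVP (4, highest other 5, 3 of 35) and the vehicle comparison (3, highest other 4, 2 of 35). There each other split with as many lists kept 3 arrays of each group together, and so still held part of the real difference. For 75 nm citrate, with 0 lists called (highest other 1, 35 of 35), the splits again say nothing.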

How the results depend on the processing

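The citrate control in place of HBSS and the lists of the size and coating contrasts were added only after seeing the data, and the other alternatives were fixed before. Of the gene values under alternatives, 5549 kept direction and side of the threshold, 896 missed it, 186 passed it newly and 37 turned sign. Of the 122 called results of named genes, 117 kept their call with cyclic loess, 103 with median scaling, 113 without background correction, 118 with the authors' table, 103 with slide as a block, 113 with array weights, 119 with trended and robust moderation and 112 with the replicate block. Without a filter 94 kept it, with both blocks 91, with only the groups compared 32 and within slide 1 4. With the ordinary two-sample test 15 of 118 kept it, within slide 2 9 of 91, and with the citrate control as control 48 of 76, where 27 missed it and 1 turned. Signal over background limits the dim probes, whose folds the offset lowers. Except where said, the cause of a change was not tested.

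Counts are given below where they left the range of 1.5 times. Without background correction they were 169 for 10 nm PVP, 778 for 75 nm PVP, 22 for 10 nm citrate, 236 for the vehicle comparison, 81 for the sizes with PVP, 3 for the sizes with citrate and 75 for coating at 75 nm. With the authors' table, in that order, they were 189, 767, 20, 240, 78, 3 and 83, with 4 for coating at 10 nm. Trended and robust moderation gave 160, 753, 16, 189, 64, 2 and 59, with 4 for coating at 10 nm and 3 for size by coating. Coating at 10 nm gave 1 with cyclic loess, 1 with median scaling, 1 with the stricter filter and 1 with both blocks. No filter gave 48 for 10 nm PVP and 58 for the vehicle comparison, as more probes were tested. The stricter filter gave 131 for 10 nm PVP, 6 for 10 nm citrate, 192 for the vehicle comparison, 48 for the sizes with PVP and 27 for coating at 75 nm. The vehicle comparison gave 30 with slide as a block, 150 with slide as a random block, 21 with both blocks and 168 with array weights. The consensus correlation of the random block was negative (-0.0263).

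Within slide 1, 10 nm PVP gave 1, 75 nm PVP 0, the vehicle comparison 0, the sizes with PVP 1, coating at 10 nm 0, coating at 75 nm 0 and size by coating 0. Within slide 2, 10 nm PVP gave 6, 75 nm PVP 4, the sizes with PVP 4 and size by coating 0. There fewer arrays were fitted, and where a slide held 1 array of a group it was assumed to vary like the others. Slide 2 gave no value against the citrate control. With only the groups compared, and so fewer arrays, the counts were 16, 20, 20 for the vehicle comparison, 5 for the sizes with PVP and 0 for coating at 75 nm. The ordinary two-sample test gave 17 for 10 nm PVP, 1 for 75 nm PVP, 3 for 10 nm citrate, 1 for 75 nm citrate, 9 for the vehicle comparison and 3 for the sizes with PVP. Against HBSS, 10 nm citrate gave 266 and 75 nm citrate 170. Against all 8 control arrays 10 nm PVP gave 181 and 75 nm PVP 923, and against the citrate control 391 and 922. Arrays of the same replicate number correlated at a mean of 0.0106 (other numbers -0.0035), with 1 of 60 pairs over 0.1, so the numbers were not taken to pair samples. Yet 12 of 24 arrays correlated best with their own number, where 6 would by chance, as a hint from the data. The replicate block gave 72, 459 and 94 for the PVP and vehicle comparisons and 3 for coating at 75 nm.

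Leaving out 1 array at a time gave 20 to 62 for 10 nm PVP, 212 to 554 for 75 nm PVP (554 without its replicate 4), 33 to 85 for the vehicle comparison, 10 to 17 for the sizes with PVP, 1 to 2 for the sizes with citrate, 1 to 3 for coating at 10 nm, 0 to 41 for coating at 75 nm (41 without 75 nm PVP replicate 4), 1 to 2 for size by coating, 1 for 10 nm citrate and 0 for 75 nm citrate. Of 11 lists shifted in the comparisons against a control, 3 were called with an estimated correlation and 30 by fry, which does not compare a list with other genes. Slide as a block gave 12 (10 shared), the values of the authors 12 (11 shared) and median scaling 10 (9 shared). Of 9 lists in the size and coating contrasts 7 were called with an estimated correlation. The overlap of 43 between both PVP sizes was 218 at an unadjusted p under 0.01 and 4 with split controls, where each size had fewer control arrays.

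Of the turned values of named genes only Spag7 had been called (-0.52 at 75 nm PVP). Among all called probes, 5 of the 78 at 10 nm PVP and 11 of the 457 at 75 nm PVP had the opposite sign against the citrate control. Nqo1 at 75 nm PVP was 0.008573 with cyclic loess, 0.08696 within slide 1, 0.003757 with array weights, 0.006987 and 0.01025 without 75 nm PVP replicates 1 and 4, and 0.03817 without HBSS replicate 4 (left-out range -0.03406 to 0.03817). Nqo1 at 75 nm citrate was 0.03805 with slide as a block, 0.09269 within slide 1, 0.03801 with both blocks, 0.1364 against HBSS, and 0.008013 and 0.03244 without 75 nm citrate replicates 2 and 4 (left-out range -0.07802 to 0.03244). Ddit3 at 10 nm PVP was 0.0001492 with median scaling, 0.02623 within slide 1, 0.005194 with array weights, 0.03345 without HBSS replicate 4 and 0.01337 without 10 nm PVP replicate 4 (left-out range -0.05687 to 0.03345), and at 75 nm citrate -0.006161 with both blocks. Txnrd1 at 75 nm citrate was 0.004378 within slide 1, 0.01367 and 0.001342 without citrate control replicates 3 and 4, and 0.01455 without 75 nm citrate replicate 2 (left-out range -0.08828 to 0.01455). Within slide 1 Col5a1 at 10 nm PVP was -0.05636 and Slc30a2 for coating at 10 nm 0.01805, and within slide 2 Mtf1 for size by coating was 0.1788. In the vehicle comparison Hmox1 was 0.1159 within slide 1 and 0.03453 without HBSS replicate 3 (left-out range -0.08215 to 0.03453). There Cdkn1a was -0.07942 without HBSS replicate 2 and -0.01802 without citrate control replicate 1 (range -0.07942 to 0.2648), and Gclm -0.003135 without citrate control replicate 2 and -0.01688 without HBSS replicate 3 (range -0.01688 to 0.03077). Slc1a2 was -0.05995 without citrate control replicate 4 (range -0.05995 to 0.1305). Cdkn1a at 75 nm citrate was -0.004412 without citrate control replicate 4 (range -0.004412 to 0.1988). With the citrate control in place of HBSS, 75 nm PVP gave 0.1216 for Spag7, -0.1468 for Mt3, -0.02322 for P4ha1 and -0.004045 for Kif20a.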

Other observations

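The list of aryl hydrocarbon receptor targets was chosen before its own values were looked up. It was not among the 31 fixed lists, and the rises of Cyp1a1 and Nqo1 in these data prompted it.

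Several fixed lists moved little in the 5 comparisons against a control. None of 12 heat shock, 16 p53, 14 fatty acid, 32 proteasome, 20 endocytosis or 4 histone genes passed limma in any of them, and the smallest camera adjusted p of these lists were 0.230, 0.398, 0.230, 0.230, 0.561 and 0.230. The inducible chaperone gene Hspa1b was detected on 0 of 24 arrays, and Ddit3 and Cdkn1a passed in none of the comparisons. Among immediate early genes Ccn2 alone passed, lower with citrate (smallest list p 0.110 after adjustment). Other lists with members that passed but no camera call had smallest adjusted p of 0.264 for 19 apoptosis regulators, 0.182 for 20 inflammatory targets, 0.561 for 55 ribosomal protein genes, 0.561 for 25 G1/S genes and 0.298 for 26 G2/M genes. For 29 lysosome genes it was 0.546, for 12 iron genes 0.398 (Hmox1 alone rose, at 10 nm PVP), for 19 selenoprotein genes 0.230, for 18 matrix genes 0.230 and for 14 actin genes 0.138.

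Tyrosine hydroxylase Th was detected on 1 of 24 arrays and the dopamine transporter Slc6a3 on 0. Of the 10 measured genes of that list Gch1 alone passed (smallest adjusted p of the list 0.561), and of 13 neuronal cytoskeleton and synapse genes Map1b alone (0.534), both at 75 nm PVP. Of other cell types, 3 astrocyte genes (0.148), 5 oligodendrocyte genes (0.148), 4 microglia genes (0.264) and 3 endothelial genes (0.768) were measured, and Gja1 alone passed among them. The fibroblast list had 1 measured gene, S100a4, which fell at both PVP sizes.

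A hypothesis for the rise of Cyp1a1 and Nqo1 at 10 nm PVP is that the aryl hydrocarbon receptor may have been active. Of 9 other known targets listed, 5 were measured, 3 of them higher, with a median log2 fold of 0.16. Camera gave p = 0.0143 (0.0224 with an estimated correlation), which met the bounds set beforehand, but adjusted over the 4 particle comparisons p was 0.0572, so the list fails that correction. Cyp1b1 rose by 0.42 (adjusted p = 0.0473), and Ahrr (0.61, 0.0652), Nfe2l2 (0.16), Serpinb2 (-0.08) and Ugt1a6 (-0.18) did not pass. In each of the other 3 particle comparisons the adjusted p of the list was 0.206. At 75 nm PVP its median was 0.17, with 4 of 5 genes higher, so a raised median was not particular to 10 nm PVP. At 10 nm and 75 nm citrate the medians were -0.07 and -0.05, with 0 and 1 genes higher.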
